A study of Mus musculus with 16 samples.

How the data were processed

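Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in haematopoietic progenitor cells described in the labels as multipotent progenitors, from mice 21 days old. The 16 samples formed 8 groups of 2 samples in 2 sets. The sets were told apart by the sample titles, and the labels do not say how they differ. Per the labels, both samples of a group name the same peak list and a signal track described as pooled, so each group had 1 peak list and no value per sample. Read depth was unknown, since no read counts were used here, and no spread between samples could be computed. The tools named in the submitters' processing notes were Bowtie2 and MACS2, with no version, and the builds mm10 and GRCm38. The tagmentation followed a published protocol, per the labels. Peak calling thresholds, read shifting, duplicate removal and filters are not given in the sources used here.

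For each peak the authors deposited a fold enrichment of the summit over the local background, which is a ratio, the −log10 of a p-value and of a q-value, and a score. The deposited score was a whole number from 413 to 1000 in each of the 8 lists, and its meaning is not given in the sources used here. If the score reflects a filter on agreement between samples, a peak missing from a list may be one on which the samples of the group disagreed. These values belong to the peak and to the authors' peak caller, and were used only to describe, rank or filter peaks within 1 list.

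Peaks on chromosomes 1 to 19, X and Y that overlapped by at least 1 bp were merged within each list, and then over the 8 lists into union regions. A union region was present in a list that held a peak inside it. A strong region had its best peak in the top 25% of its own list by −log10 p. A strong gain was a strong region of the mutant list with no peak in the wild-type list of the same set, and a strong loss was the reverse. With 1 list per group, no p-value between genotypes was computed. The error was described by lists of equal genotype from the 2 sets, 1 pair of wild-type lists and 1 pair of Flt3-ITD lists. Such pairs also hold any difference between the sets, so they do not measure error within a set. Overlaps between comparisons that share a wild-type list were counted again with a different wild-type list for each mutant, because n1 × n2 / N takes no account of the shared list. This recount kept a gain only if absent from both wild types, and a loss only if strong in both, so it could not be higher. The simulation of unchanged lists, 100 draws in which the states of each region were permuted over the 8 lists, gave a mean of 70.2 to 72.3 shared gains and 38.1 to 39.6 shared losses for every pair whatever its counts, even for lists with 12 and 4 losses, and was not used as a reference.

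The gene table used was that of assembly GRCm38.p6, the build of the peaks. It gives no strand, so the planned nearest transcription start site was replaced by the nearest span of a protein-coding gene within 100 kb. Exons, introns and untranslated regions were not known, and a gene named beside a region is its nearest gene only. Of 122020 union regions, 110444 (90.5%) had such a gene. For 16 gene lists fixed before the data were examined, 356 of 359 entries were matched. The number of list members with a region of interest was given as a percentile among 10000 random lists of protein-coding genes matched on the number of union regions per gene, as a description and not a test of genotypes. The lists were interferon response, stem cell self-renewal, lymphoid priming, granulocyte-monocyte, megakaryocyte-erythroid, mast, basophil and eosinophil, dendritic cell, B cell, T and NK cell, stroma and endothelium, STAT5 targets, MAPK feedback, HOX and MEIS, fetal and neonatal progenitor, haematopoietic transcription factors, and a housekeeping control. Motif analysis needed a genome sequence and was not run.

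The named regions were fixed by rule. They were the 8 strong gains and 8 strong losses with the highest −log10 p in each mutant list, the 8 per direction shared by both Flt3-ITD comparisons (by the lower of the values), 1 per gene, on chromosomes 1 to 19 and X, up to 4 members of a gene list outside the central 95% of random lists, and Flt3, Runx1, Nup98 and Hoxd13. Not every region of the rule is printed.

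After the planned gene lists had left nearly every list inside the random range, further comparisons were chosen with the data in view. Within each set, regions present in both lists with a mutation and absent from both without it were counted, with the mixed split of the same 4 lists as background. Regions in all 4 Flt3-ITD lists and no other, and in both NUP98-HOXD13 lists and no other, were also counted. These comparisons were made on the lists as deposited and on the 84080 peaks with the highest −log10 p of every list, the number of the shortest list, and both values are given. With equal numbers a region can count as gained because a weaker peak of another list fell below the limit. They came to 512 gene list percentiles over 16 patterns. The splits were also run with genes within 20 kb and with the 500 bp margin, to see whether a list kept its place, and these runs are not counted among the 512. Shifts in the rank of a region between lists of equal length were tried as well and not used, because their SD between lists of equal genotype (13.0 and 14.9 percentile points by −log10 p) lay within the range for mutant and wild-type lists (10.1 to 16.5).

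Alternatives were a −log10 q of at least 5, equal numbers of peaks, an overlap of at least 50% of the shorter region, absence only if no peak lay within 500 bp, strong as the top 10%, ranking by fold, absence in both wild-type lists, the wild type of the other set, no sex chromosomes, and genes within 20 kb. On simulated changes in a copy of the set-1 wild-type list (74504 regions), 200 of 200 planted gains and 200 of 200 planted losses were recovered. The planted changes lay well above the limit for strong, and the copy was otherwise identical. Recovery was thus a check of the code only, and says nothing of missed or false changes between real lists. Of 1000 simulated random gene lists over 21883 genes, 49 fell outside the central 95%, and 1000 of 1000 lists with 12 planted genes of 20 lay above it. Lists with fewer planted genes were not tried. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, bedtools 2.31.1 and matplotlib 3.10.9.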

Results

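Open chromatin was mapped in haematopoietic progenitors of mice 21 days old. Set 1 held wild type, Flt3-ITD (an internal tandem duplication that activates the receptor tyrosine kinase Flt3), Runx1-het (loss of 1 copy of a haematopoietic transcription factor) and their combination. Set 2 held wild type, NUP98-HOXD13 (a leukaemia fusion gene), Flt3-ITD and their combination. Each of the 8 groups had 2 samples and 1 deposited peak list, so none of the values below has a replicate error, and read depth was unknown. The study title concerns how Flt3-ITD changes cell identity together with cooperating mutations, and how far this depends on interferon.

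The lists held 74304 to 91059 regions except for 1. In set 1, wild type held 74304 regions, Flt3-ITD 82158, Runx1-het 85467 and Flt3-ITD/Runx1-het 84132. In set 2, wild type held 91059, NUP98-HOXD13 80373, NUP98-HOXD13/Flt3-ITD 76917 and Flt3-ITD 59935. The regions covered 45.5 Mb in set-1 wild type, 53.6 Mb in set-2 wild type and 34.8 Mb in set-2 Flt3-ITD. Median −log10 p of a peak, the authors' value, was 33.5 in set-1 wild type, 38.5 in set-2 wild type and 15.8 in set-2 Flt3-ITD. Of 122020 union regions, 41626 were present in all 8 lists and 23122 in 1 list.

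**Figure D1:**
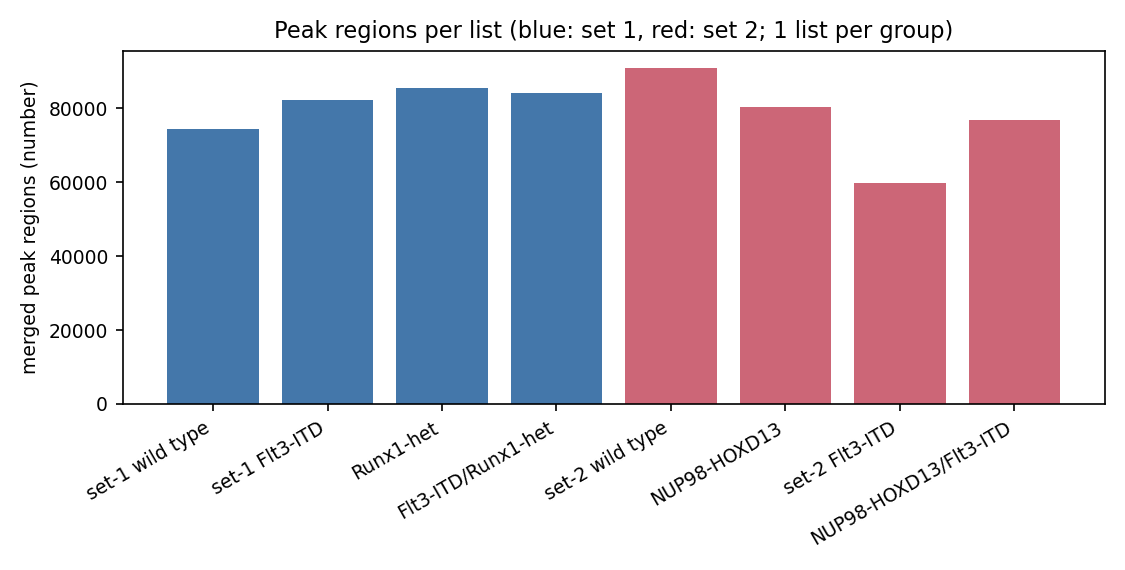
Number of merged peak regions in each of the 8 peak lists (bars from 0; blue, set 1; red, set 2), 1 list per group and so no error bars. The set-2 Flt3-ITD list is the shortest, at 59935 regions.

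The genes that the genotypes name gave no check of the labels. Within 2 kb of Flt3 (chromosome 5, 147330741 to 147400489), the lists held 5 to 13 regions, and within 2 kb of Runx1 (chromosome 16, 92601466 to 92826074) 9 to 17. Nup98 (chromosome 7, 102119400 to 102210166) held 1 region in each list. Hoxd13 (chromosome 2, 74668225 to 74671603) held 2 regions in the 4 set-1 lists and in set-2 wild type, and 1 in each of the 3 set-2 mutant lists. Accessibility at these genes does not read a duplication, a lost copy or a transgene.

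Agreement between lists did not follow genotype alone. The Jaccard index was 0.686 for the 2 wild-type lists and 0.609 for the 2 Flt3-ITD lists. Set-1 wild type shared more with the set-1 mutants Flt3-ITD (0.712) and Runx1-het (0.712) than with the other wild type. The highest of the 28 values was 0.721, between set-1 Flt3-ITD and Flt3-ITD/Runx1-het, and NUP98-HOXD13 with its double mutant reached 0.701. Every pair with set-2 Flt3-ITD lay at or below 0.621. The index is limited by unequal list lengths, and this list was the shortest. Of its 57245 union regions, 53228 were present in set-2 wild type, though that pair had the lowest index, 0.577. The low values thus do not show that its regions were different ones.

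**Figure D2:**
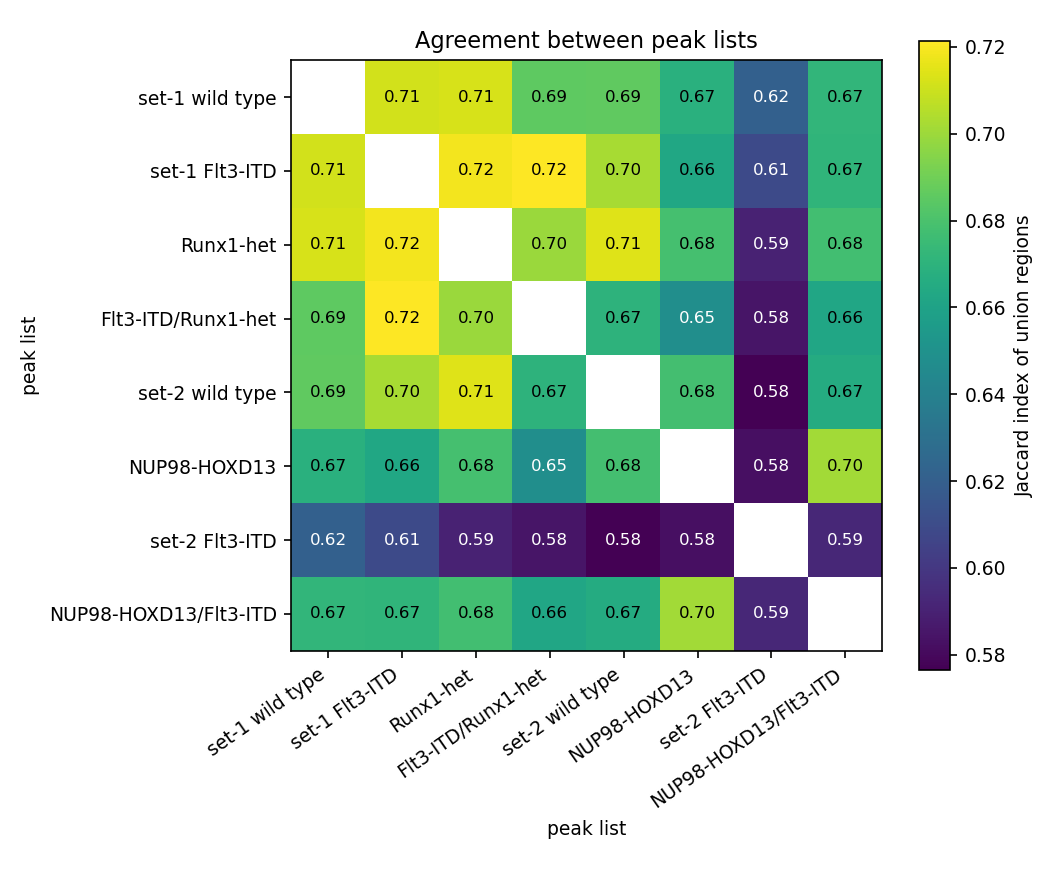
Jaccard index of union regions (colour and number) for every pair of the 8 peak lists, which are on both axes. The lowest values are those of the set-2 Flt3-ITD list, the shortest, from 0.577 to 0.621.

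Flt3-ITD in set 1 had 135 strong gains and 12 strong losses, and the balance turned to 40 gains and 126 losses against the set-2 wild type. The gains with the highest −log10 p lay nearest to Col19a1 (chromosome 1, start 24613000, −log10 p 923.6), Ncam2 (327.8), Dpp4 (182.0), Pclo (180.2), Ptprd (148.0), Otc (141.1), Crisp1 (132.1) and Klk4 (132.1). The losses were led by Rasl11b (chromosome 5, start 74194780, 327.4), Plcl1 (266.3), Serp1 (234.6), Car8 (213.1), Tnfrsf23 (143.7), Cadps2 (97.2) and Pdcd10 (92.9). Of the 135 gains, 19 were absent from the set-2 wild type as well. The regions at Col19a1, Otc and Klk4 were present in 7 of the 8 lists and missing from set-1 wild type. No list of regions prone to artefacts was used here, so the Col19a1 region, which had the highest value, was not checked for one.

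Runx1-het had 83 strong gains and 4 strong losses, but 7 and 88 against the set-2 wild type. The gains were led by the same Col19a1 region (892.2), followed by Pptc7 (146.2), Cacna2d3 (146.0), Thnsl2 (142.6), Cyth4 (127.1), Klk4 (124.9), Fbxo40 (121.3) and Osbpl8 (120.7). None of the 83 was absent from both wild-type lists (0 regions). The 4 losses lay nearest to Zfp329 (363.0), Clec4a3 (214.0), Acbd3 (94.2) and Il12b, which encodes an interleukin subunit (81.2), and each of these regions was present in the other 7 lists.

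Flt3-ITD/Runx1-het had 189 strong gains and 32 strong losses, but 108 and 372 against the set-2 wild type. Its gains were led by Col19a1 (966.1), Ncam2 (321.6), Syt1 (275.1), Pclo (257.4), Dpp4 (234.8), Col6a3 (186.3), Gda (181.6) and Adamtsl1 (166.7). Its losses were led by Polrmt, the mitochondrial RNA polymerase (284.5), Clba1 (230.3), Ppm1h (117.8), Tenm3 (112.2), Slc24a2 (108.2), Tph2 (105.5), Osr1 (98.9) and Atp10b (93.8). Of the gains, 55 were absent from both wild-type lists.

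NUP98-HOXD13 had 96 strong gains and 336 strong losses, but 359 and 96 against the set-1 wild type. The gains lay nearest to Klhl3 (157.1), the major histocompatibility gene H2-Q6 (149.6), Slc35f1 (148.8), Ltbp1 (143.4), Gramd1b (132.3), Morc1 (128.5), Plekha5 (116.8) and Slc24a2 (116.1). The regions at Klhl3, Slc35f1, Gramd1b, Plekha5 and Slc24a2 were present in 2 of the 8 lists. The losses were led by Atp2b2 (591.6), Vps13d (539.1), Mgat4b (403.4), Slco6d1 (345.0), Adgrb1 (303.9), Clint1 (274.2), Chrm3 (273.4) and Samsn1 (271.8). Of the 96 gains, 76 were absent from both wild-type lists.

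Flt3-ITD in set 2 had 19 strong gains and 1097 strong losses, and 74 and 458 against the set-1 wild type. The gains were led by Syt1 (67.0), Col6a3 (56.9), Trpm3 (41.7), Agbl1 (41.0), Ptprd (40.1), Olfr1258 (39.8), Gm4951 (36.2) and Rpp25 (35.8). The losses were led by a region nearest to Cdk1, a cell cycle kinase (280.9), and by Rab31 (273.8), Manea (265.6), Cfap61 (259.5), Ctsc (259.1), Kcnk9 (250.6), Lama4 (250.1) and Ctnna3 (241.2). Each of these 8 lost regions was present in the other 7 lists.

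NUP98-HOXD13/Flt3-ITD had 95 strong gains and 505 strong losses, but 362 and 126 against the set-1 wild type. The gains were led by Ptprd (150.7), Mbd1 (137.5), Map4k5 (133.2), Ltbp1 (132.7), Gramd1b (127.2), Stx2 (124.9), Grxcr1 (123.6) and H2-Q6 (116.5), and 71 of the 95 were absent from both wild-type lists. The losses were led by Mgat4b (403.4), Daxx (396.0), Slco6d1 (345.0), Clstn2 (339.0), Pid1 (323.0), Nipsnap2 (314.5), Adgrb1 (303.9) and Ndn, a gene of the stem cell list (281.7).

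Lists of equal genotype also differed in strong regions. Set-2 wild type had 320 strong regions missing from set-1 wild type, led by the same Col19a1 region (2648), and 1 in the reverse direction, at H2-Q6 (125.7). Set-2 Flt3-ITD had 15 strong regions missing from set-1 Flt3-ITD and lacked 719 of that list. The 83 to 189 strong gains of the set-1 mutants lay below the 320 between wild-type lists. Of the strong losses of the set-2 mutants, 336 and 505 lay between the 320 and the 719, and 1097 above both. NUP98-HOXD13, set-2 Flt3-ITD and their double mutant had 96, 19 and 95 strong gains over set-2 wild type, where set-1 wild type had 1. Set-1 wild type had 12, 4 and 32 strong regions missing from Flt3-ITD, Runx1-het and their double mutant. These reference pairs come from different sets and hold any difference between the sets. The 719 also involves the shortest list. With equal numbers of peaks, which also narrows what counts as strong in every longer list, the strong losses fell to 66 in NUP98-HOXD13, 96 in NUP98-HOXD13/Flt3-ITD and 112 in set-2 Flt3-ITD.

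**Figure D3:**
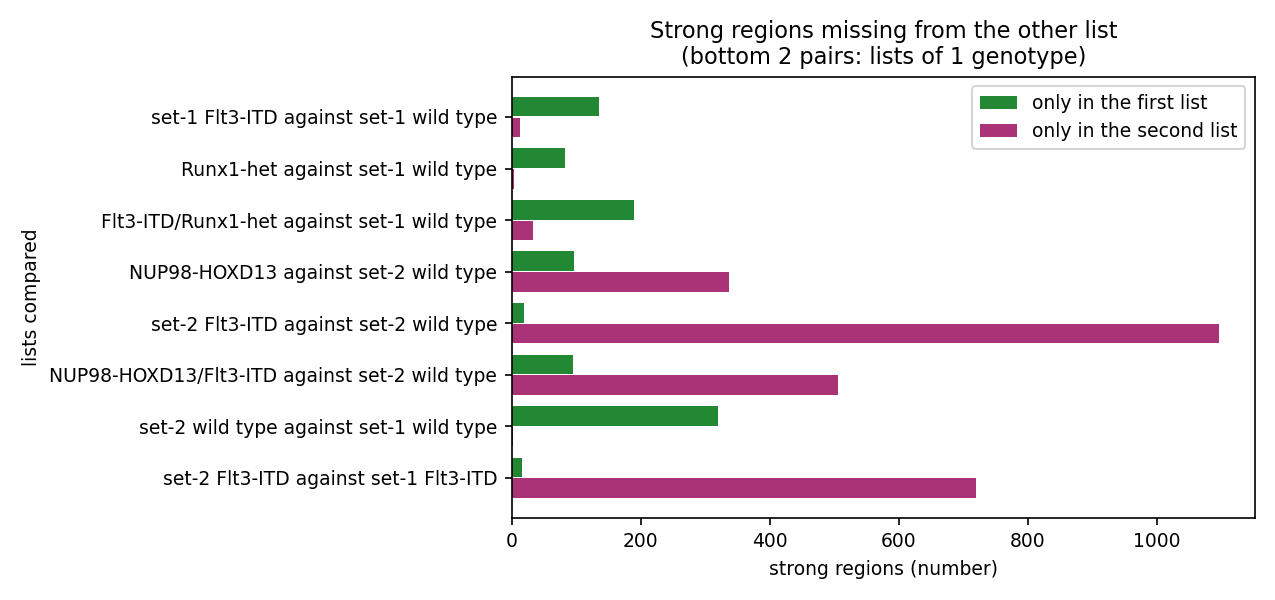
Number of strong regions present only in the first list (green) or only in the second (purple) of each pair on the vertical axis. The last 2 pairs compare lists of 1 genotype from different sets, and reach 320 and 719.

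The gene lists were rarely outside the random range on strong gains and losses. Of 192 percentiles (16 lists, 6 mutants, both directions), 1 lay outside the central 95%, where 9.6 would be so for independent lists with many hits. It was the fetal and neonatal progenitor list among the losses of NUP98-HOXD13/Flt3-ITD, with 3 of 14 members against a random mean of 0.487 (percentile 99.4). The members were the mannose receptor gene Mrc1 (−log10 p 138.0), the RNA-binding protein gene Igf2bp2 (123.7) and the endothelial cadherin gene Cdh5 (104.5). With equal numbers of peaks, 0 lists lay outside on strong changes, so this result was not kept. The interferon response list had 0 members among strong changes of the 3 set-1 mutants. None of the 32 percentiles between the wild-type lists lay outside (0). Where strong changes were few, random lists seldom had any member, so those percentiles had little power. This holds less for the 1097 losses of set-2 Flt3-ITD and the 505 of NUP98-HOXD13/Flt3-ITD.

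Flt3-ITD was the genotype that both sets shared. Regions in both Flt3-ITD lists and in neither wild-type list numbered 923, against 547.4 for independent gains, and 3959 showed the reverse, against 2579. Among the patterns that follow no mutation, set-1 Flt3-ITD and set-2 wild type alone shared 6338 regions, against 4780, and set-1 wild type and set-2 Flt3-ITD alone 344, against 295.4. Both set-1 lists alone shared 2450 regions and both set-2 lists alone 1677. The gains with the highest lower −log10 p were at Syt1 (chromosome 10, 108991248 to 108991935, inside the gene span, 67.0), Col6a3 (56.9), Agbl1 (41.0), Ptprd (40.1), Olfr1258 (39.8), Cdh13 (32.3), Clvs2 (30.7) and Enpp6 (30.4). The losses were led by Susd1 (89.0), Hsd17b4 (74.3), Nudt9 (70.7), Slc37a3 (67.5), Gpr174 (65.4), Sdk2 (63.3), Arhgap25 (61.5) and Pcdh15 (61.5). The Syt1 region was present in all 4 lists with Flt3-ITD and in none of the other 4 lists (0).

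Compared with the other lists of their set, the double mutants alone had few strong gains and more strong losses. A gain had to be absent from wild type and both single mutants, while a loss had to be kept by these. Such counts were not made for single mutants. Of the 1097 strong losses of set-2 Flt3-ITD, 95.3% were present in NUP98-HOXD13 and 91.6% in NUP98-HOXD13/Flt3-ITD. More losses than gains thus cannot be read as a trait of the double mutants. Flt3-ITD/Runx1-het had 1 strong gain absent from wild type and both single mutants, inside Ano7 (chromosome 1, 93391419 to 93392125, −log10 p 87.3), and 31 strong losses kept by both single mutants, led by Polrmt and Clba1. NUP98-HOXD13/Flt3-ITD had 4 such gains, of which those with a gene within 100 kb were inside Iqgap2 (68.5, also present in Runx1-het and Flt3-ITD/Runx1-het) and Specc1 (63.5), and 294 such losses, led by Daxx, Clstn2 and Pid1. With equal numbers of peaks, such losses fell to 7 in Flt3-ITD/Runx1-het and 58 in NUP98-HOXD13/Flt3-ITD. Flt3-ITD and Flt3-ITD/Runx1-het shared 62 strong gains. NUP98-HOXD13 and its double mutant shared 39 strong gains and 142 strong losses. When these mutants were set against different wild-type lists, a shared gain had to be absent from both wild types and a shared loss strong in both. The counts could thus only stay or fall. Of these overlaps, 11 shared gains were left in set 1, and 28 shared gains and 22 shared losses in set 2. For the other partner of each double mutant, the 32 gains shared by Runx1-het and Flt3-ITD/Runx1-het fell to 0. That fall was fixed in advance, since none of the 83 strong gains of Runx1-het was absent from both wild-type lists. The 92 losses shared by set-2 Flt3-ITD and NUP98-HOXD13/Flt3-ITD fell to 5, and their 6 shared gains to 5. The recount therefore does not separate a shared change from an effect of the shared list. The wild-type lists could not be split further, so part of each overlap may come from the shared list.

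The following comparisons were chosen after the data were examined, and set both lists with a mutation against both without it within a set. The HOX and MEIS list stood out with NUP98-HOXD13, whose 2 lists together gained 3420 regions and lost 2526 (3146 and 2640 with equal numbers of peaks). Of 30 HOX and MEIS genes, which specify position and progenitor state, 10 had a gained region against a random mean of 4.35 (percentile 99.9), and 11 against 3.70, above nearly all random lists, with equal numbers. They included Hoxc4 with 3 regions (chromosome 15, 103018708 to 103019061, −log10 p 42.0), Hoxb3 (chromosome 11, 96306853 to 96307239, 36.0), Hoxb8 (21.5) and Hoxb9 (21.3). With equal numbers, the region at Hoxb5 (28.05) and the strongest at Hoxc6 (175.8) also counted as gained. As deposited, set-2 wild type held a peak in each, which fell below the limit when the lists were shortened. The fetal and neonatal progenitor list had 7 of 14 members, including Lin28b (21.1), Hmga2 (18.4), Igf2bp1 (22.9) and Igf2bp3, at percentile 98.1, and 5 members at 86.5 with equal numbers. The STAT5 target list had 1 of 20 members among these gains (percentile 0.66), and 3 members at 14.0 with equal numbers. Among the losses, the lymphoid priming list had 1 of 22 members, at Ebf1 (7.85, percentile 2.39, and 2.68 with equal numbers). The interferon response list had 0 of 40 (percentile 2.72, and 1.88 with equal numbers). Against random blocks of neighbouring genes, both lists lay inside the random range. Lymphoid priming lay there at 2.545, and 3.09 with equal numbers, and interferon response at 3.85 and 2.82.

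**Figure D4:**
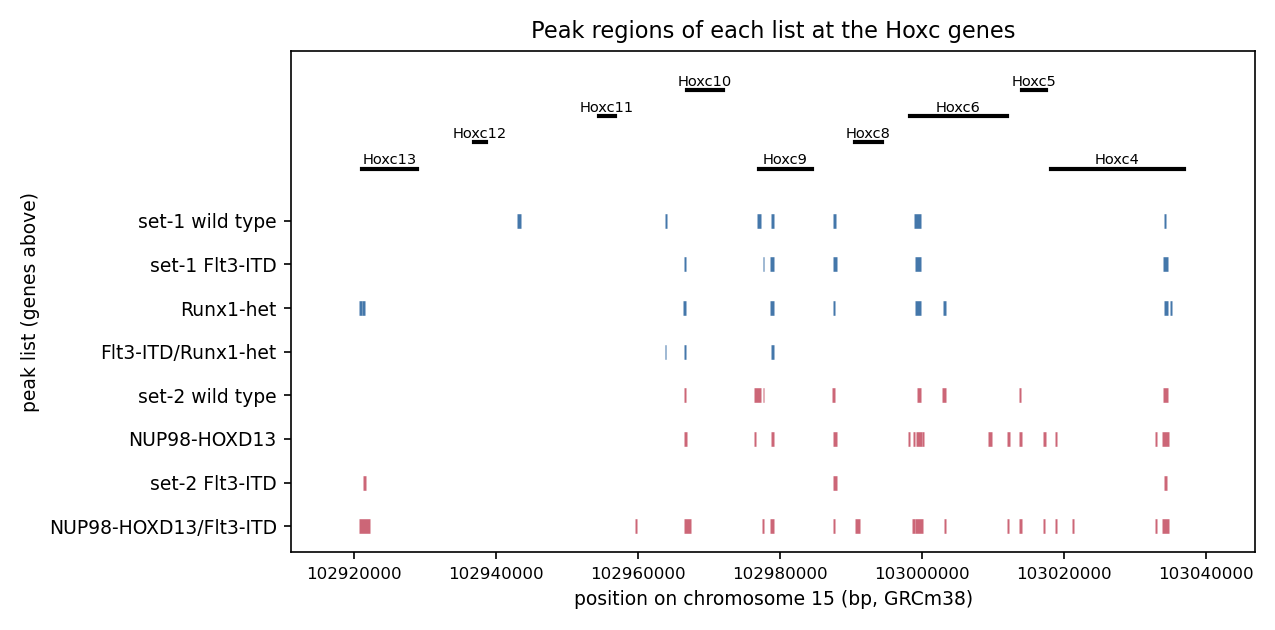
Peak regions (coloured bars) of each list at the Hoxc genes (black bars show gene spans) against position on chromosome 15 in bp, GRCm38. Regions gained at Hoxc4, such as 103018708 to 103019061, are present in the NUP98-HOXD13 and NUP98-HOXD13/Flt3-ITD lists.

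STAT5 targets, genes regulated by a transcription factor downstream of Flt3-ITD, stood out with Flt3-ITD in set 2 and, depending on the number of peaks used, in set 1. In set 2 the Flt3-ITD lists gained 552 regions and lost 5494 (900 and 2622 with equal numbers). Of 20 STAT5 targets, 4 had a gained region against a random mean of 1.02 (percentile 99.1, but 96.5 and inside the random range with a 500 bp margin), at the cytokine gene Osm (chromosome 11, 4232604 to 4233092, 15.7), Bcl6 (13.9), Cdkn1a (12.1) and Socs1 (8.18). With equal numbers they were 10 against 1.74, above nearly all random lists. The additions were Mcl1 (17.65), the feedback inhibitor genes Cish (14.7) and Socs2 (11.2), Pim1, Spi1 and Bcl2. None of these additions was gained as deposited. The set-2 Flt3-ITD list, the shortest, kept all its peaks, while weaker peaks of the lists without Flt3-ITD fell below the limit. The STAT5 target list had 3 of 20 members among the losses (percentile 1.08, and 2 members at 11.2 with equal numbers). As deposited these were Bcl2, Ccnd1 and Cdkn1a, so Cdkn1a had both a gained and a lost region. In set 1 the Flt3-ITD lists gained 3402 regions and lost 2170 (2528 and 1804 with equal numbers). Among these gains the STAT5 target list had 7 members against 5.40 (percentile 80.1), which is inside the random range. With equal numbers it had 9 against 4.24 (percentile 99.2). Losses in set 1 lay at Socs1 (17.8), Socs2 (9.89) and Pim1 (8.24), and with equal numbers at Bcl6, Bcl2 and Socs1. The same Osm region (59.0) and the same Cish region (chromosome 9, 107307402 to 107308328, 29.9) were gained in both sets with equal numbers. As deposited, the Osm region was gained in set 2 alone and the Cish region in neither set, since Runx1-het and set-2 wild type also held a Cish peak there, which fell below the limit when the lists were shortened.

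Other lists moved with Flt3-ITD in 1 set or under 1 number of peaks. In set 1 the dendritic cell list had 6 of 17 members among the losses, with Ccr9 (25.5), Tcf4 (13.5), Zbtb46 (40.4) and Runx2 (30.6), at percentile 99.1, and 6 at 99.6 with equal numbers, while in set 2 it had 1 member among the gains at 66.7, and 4 at 99.0 with equal numbers. The interferon response list had 7 of 40 members among the set-1 losses against 2.53, with Ifi44 (23.5), Ifitm3 (13.3), Ifitm1 (28.3) and Zbp1 (21.7), at percentile 99.5, and 4 members at 87.3 with equal numbers; in set 2 it had 5 against 6.18. The megakaryocyte-erythroid list had 6 of 26, with Pf4 (35.5), Aqp1 (22.3) and Selp (17.1), at 99.2, and 4 members at 94.1 with equal numbers. Among the set-1 gains, the stem cell list (8 of 26, and 10 with equal numbers, with Mllt3, Hlf and Socs2) lay at 75.5 and 98.9, and the haematopoietic transcription factor list (11 of 20, with Bcl11a, Fli1, Runx3 and Runx2) at 93.0 and 98.7. The stroma and endothelium list had 9 of 19 members among the set-2 losses, with Kdr (24.4), Pdgfra (16.8), Emcn (25.2) and Pdgfrb (23.6), at 98.3, and 3 members at 64.9 with equal numbers.

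Runx1-het lists gained 2903 regions and lost 1398 (1429 and 1233 with equal numbers), and 0 of the 16 lists lay outside the random range in either direction with either number of peaks. In set 1, regions at the Y-linked genes Ddx3y, Uty and Eif2s3y were present in both Runx1-het lists and absent from the other lists of the set, so this split coincided with signal at these genes, though not at Kdm5d, which is Y-linked as well. The granulocyte-monocyte, B cell, T and NK cell, mast, basophil and eosinophil, MAPK feedback and housekeeping lists lay inside it for every mutation split with both numbers of peaks.

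Patterns over all 8 lists were counted among these percentiles. Among regions in both NUP98-HOXD13 lists and no other, the HOX and MEIS list had 7 members against 1.65, and 6 against 1.51 with equal numbers. The B cell list, with Pax5 (23.8) and Ebf1 (11.8), had 5 of 15 against 0.937 there, but 1 member at percentile 64.4 with equal numbers. Among regions lost in all 4 Flt3-ITD lists, the interferon response list had 2 members, Ifi44 (14.2) and Zbp1 (12.8), at percentile 97.6, and 1 member at 89.6 with equal numbers. Among those gained, the STAT5 target list had 2 members with equal numbers (98.8), the Osm and Cish regions above.

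These percentiles were many. Of the 512 examined, 29 lay outside the central 95%, where 25.6 would be so for independent lists with many hits. Sparse patterns do not meet that condition. Among regions gained in all 4 Flt3-ITD lists, the interferon response list had 0 members against a random mean of 0.094, at percentile 45.5, and could not lie lower. The number of results outside to be met by chance is therefore not known. Mutation splits gave 10 of 128 with the lists as deposited and 8 of 128 with equal numbers, against 6.4 on the same reckoning. The mixed splits, which set wild type and the double mutant against the single mutants, gave 3 of 64 with each, against 3.2. As deposited these were lymphoid priming (percentile 99.6) in set 1, and stem cell self-renewal, just past the limit, and B cell (97.9) in set 2.

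**Figure D5:**
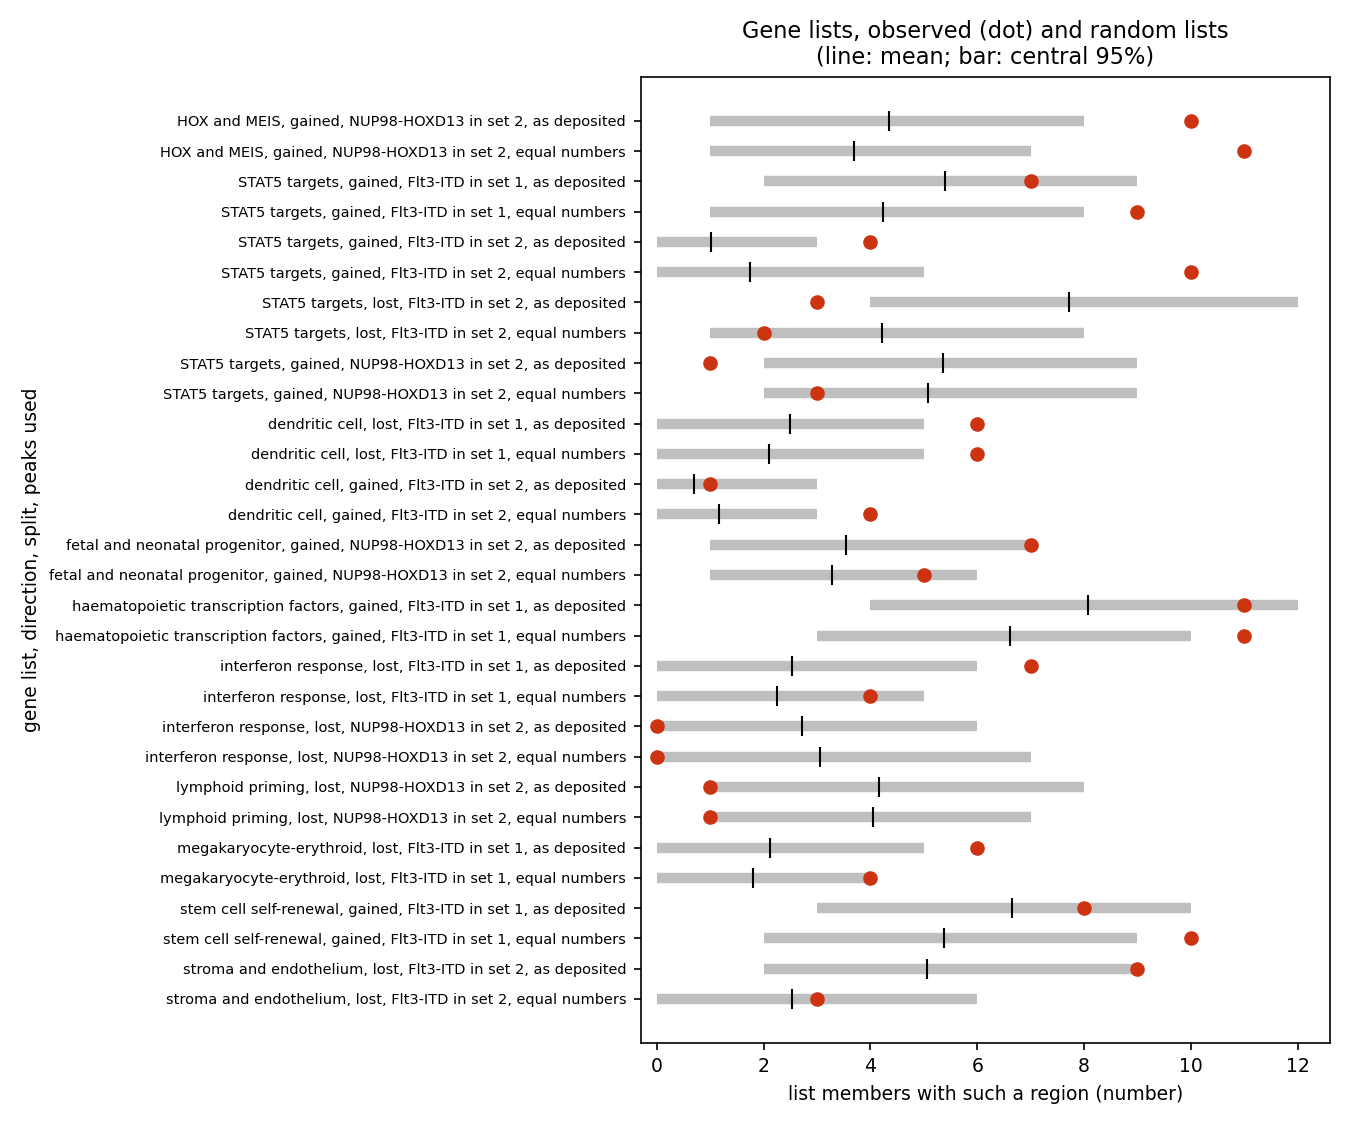
Number of gene list members with a gained or lost region (red dots, horizontal axis) beside the mean (black line) and central 95% (grey bar) of 10000 random lists, for every mutation split and list outside that range with the lists as deposited or with equal numbers of peaks. The STAT5 target list with Flt3-ITD in set 2 reaches 4 and 10 members against means of 1.02 and 1.74.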

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

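All tests in this part except that of the set-1 Flt3-ITD list against the missing regions were chosen after the result was seen. The number of regions in Flt3-ITD alone differed from wild type in opposite directions in the 2 sets. Set-1 Flt3-ITD held 7854 regions more than its wild type, and set-2 Flt3-ITD differed by -31124 from its own. The double mutants held fewer regions than the lists with the partner mutation alone, at 84132 against 85467 for Runx1-het and 76917 against 80373 for NUP98-HOXD13. Both differences were smaller than that between the wild-type lists. The sequence covered did not fall in both: it was 47.9 Mb against 49.9 Mb for Runx1-het, but 50.4 Mb against 48.7 Mb for NUP98-HOXD13. With 1 list per group the difference between the sets was not tested. Whether Flt3-ITD cells have fewer open regions in general could not be decided, since the rise of 7854 in set 1 was smaller than the difference of 16755 regions between the wild-type lists. A lower depth or yield of the set-2 Flt3-ITD list stays open. Of its 1097 strong losses, 96.6% were present in the set-1 Flt3-ITD list and 91.6% in NUP98-HOXD13/Flt3-ITD, which is consistent with regions missed in that list, but a change in these mice alone would give the same values.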

How the results depend on the processing

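No paired analysis was possible because each group had 1 peak list made from both samples, so that no sample could be blocked or left out. Motifs at either width were not run, for lack of a genome sequence. Of the alternatives chosen before the data were examined, 69 values stayed within 1.5 times the main value and 72 did not. Numbers of regions per list, and strong gains and losses with a 50% overlap, a 500 bp margin or no sex chromosomes, all stayed within it. Values below are in the order set-1 Flt3-ITD, Runx1-het, Flt3-ITD/Runx1-het, NUP98-HOXD13, set-2 Flt3-ITD, NUP98-HOXD13/Flt3-ITD. Depth could not be examined, and the cause of a move was not tested unless stated.

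With a −log10 q of at least 5, strong gains were 75, 45, 122, 50, 8 and 58, and strong losses, for the last 4 comparisons, 14, 221, 662 and 330. With equal numbers of peaks, which also narrows what counts as strong in the longer lists, strong gains were 29, 9, 56 and 42 for the first 4 and 39 for the last, and strong losses 5 for the first and 7, 66, 112 and 96 for the last 4. With the top 10%, which holds fewer regions by construction, gains were 6, 2, 10, 2, 1 and 2, and losses 4, 2, 2, 16, 7 and 25. Ranked by fold, gains were 704, 507, 853, 236, 65 and 313, and losses 110, 78, 200, 1023, 3009 and 1476. With absence in both wild-type lists, gains were 19, 0 and 55 in set 1 and 9 for set-2 Flt3-ITD. With the wild type of the other set, gains were 40, 7, 108, 359, 74 and 362, and losses 126, 88, 372, 96, 458 and 126.

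Flt3-ITD changes found in both sets fell to 9 gained and 1 lost among strong peaks, and the lost ones to 2274 with equal numbers. Strong losses only in the double mutant were 7 (Flt3-ITD/Runx1-het) and 58 (NUP98-HOXD13/Flt3-ITD) with equal numbers, and 2 and 13 with the top 10%. Strong gains only in the double mutant were 0 and 0 with the top 10%, and 1 for NUP98-HOXD13/Flt3-ITD with equal numbers. Gene lists outside the random range on strong changes numbered 2 within 20 kb and 0 with equal numbers, against 1.

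The remaining values belong to comparisons chosen after the data were examined, of which 58 counts or percentiles stayed within 1.5 times the main count or on the same side of the limits of the central 95%, some after large moves. With equal numbers, regions gained with Runx1-het were 1429, those gained and lost with Flt3-ITD in set 2 were 900 and 2622, and those lost in all 4 Flt3-ITD lists were 138. With equal numbers, these percentiles entered the outer range: STAT5 targets gained with Flt3-ITD in set 1, 99.2, dendritic cell gained in set 2, 99.0, haematopoietic transcription factors gained in set 1, 98.7, stem cell self-renewal gained in set 1, 98.9, and interferon response lost with NUP98-HOXD13, 1.88. These left it with equal numbers: STAT5 targets lost with Flt3-ITD in set 2, 11.2, and gained with NUP98-HOXD13, 14.0, fetal and neonatal progenitor gained with NUP98-HOXD13, 86.5, interferon response lost with Flt3-ITD in set 1, 87.3, lymphoid priming lost with NUP98-HOXD13, 2.68, megakaryocyte-erythroid lost in set 1, 94.1, and stroma and endothelium lost in set 2, 64.9. Within 20 kb, lymphoid priming lay at 5.30 and stroma and endothelium at 65.9. With a 500 bp margin, STAT5 targets gained in set 2 lay at 96.5, interferon response lost in set 1 at 96.3 and lymphoid priming at 3.13. The HOX and MEIS list gained with NUP98-HOXD13 and the dendritic cell list lost with Flt3-ITD in set 1 stayed outside in the 3 settings run.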

Other observations

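All tests of this part were chosen after the result was seen, except those against blocks of neighbouring genes and that of distance to Flt3. Regions in exactly 2 of the 8 lists were most often shared by NUP98-HOXD13 and its double mutant, with 1145 regions as deposited and 1154 with equal numbers of peaks, the highest of the 28 pairs in each. With a −log10 q of at least 5 they were second, at 1110, below set-1 Flt3-ITD and Flt3-ITD/Runx1-het at 1142. The strongest lay nearest to Gramd1b (−log10 p 127.2), Klhl3 (115.9), Grxcr1 (111.9) and Sema3e (96.5), and one lay 21876 bp from Lmo2, a haematopoietic transcription regulator (77.5). These genes were chosen after their values were seen. Y-linked genes differed within set 1. Regions within 2 kb of Ddx3y, Uty and Eif2s3y were absent from set-1 wild type and set-1 Flt3-ITD (0 each) and present in the other 6 lists, so within set 1 they split the lists as Runx1-het does. Kdm5d, also Y-linked, did not follow this, with 1 region in Flt3-ITD/Runx1-het and in NUP98-HOXD13 and 0 in the other lists. The X-linked gene Xist did not mirror the Y-linked genes in set 1. It held 1 region in wild type, 3 in Flt3-ITD, 4 in Runx1-het and 3 in Flt3-ITD/Runx1-het.

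Regions in all 4 Flt3-ITD lists and no other numbered 71, and 234 showed the reverse, a sum of 305. Of the 35 splits of the 8 lists into 4 and 4, 5 gave as many, so chance was not excluded, and the highest other split gave 484. The 4 other splits as large all put more lists of 1 set on a side. Among the 18 splits with 2 lists of each set per side, 1 gave as many, the real one, and the highest other gave 283. Independent changes in the 2 sets would give 15.4 regions gained and 97.7 lost in both, and 23.7 and 49.3 with equal numbers, where 102 and 138 were found. Opposite changes lay nearer to independence, at 173 against 153.2 and 12 against 9.82, and at 58 against 69.1 and 18 against 16.9 with equal numbers. With equal numbers the sum was 240, 4 of 35 splits gave as many, and the split by set gave the most, 483. Among the 18 splits with 2 lists of each set per side, the highest other then gave 230, close to the 240.

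STAT5 targets among the regions gained with Flt3-ITD are a hypothesis found and examined on the same data. More granulocyte-monocyte cells stay open, since the highest percentile of that list over both sets and both numbers of peaks was 80.7, inside the random range, which does not exclude them. Neighbouring genes counted more than once had little room, since the 20 targets formed 18 runs of neighbours. The comparison with random blocks of neighbouring genes therefore differed little from the ordinary one and adds little to it. In set 2 the list stayed at percentile 99.3 or above against such blocks. In set 1 that percentile was 83.9 with the lists as deposited and 99.3 with equal numbers. In the 10 other directed splits of a set into pairs, the list reached at most 76.85 as deposited. This decides nothing beside the 80.1 of set 1, which is itself inside the random range. With equal numbers those splits reached at most 78.9, and the lower of the Flt3-ITD splits 99.2. The answer thus depends on the number of peaks used. Chance over the 512 percentiles stays open, because results as high as the weaker set would be met 138.4 times with the lists as deposited and 6.21 times with equal numbers, and those of set 2 alone 7.85 and 0.000512 times. The last value rests in part on genes gained only after the other lists were shortened.

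HOX and MEIS genes among the regions gained with NUP98-HOXD13 are likewise a hypothesis. Since HOX genes lie in clusters, regions of neighbouring genes could be counted more than once, but against random blocks of neighbours the list stayed at percentile 99.7 or above. In the 11 other directed splits it reached at most 92.8. Chance over the 512 percentiles is open with the lists as deposited, where 1.15 results as high would be met. It is less so with equal numbers (0.0358). Both values rest on random lists that take no account of neighbouring genes. The value with equal numbers also rests in part on Hoxb5, gained only after a set-2 wild-type peak there fell below the limit. A biological effect of the fusion gene and a difference between litters or sorts remain untested.

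DNA linked to the engineered Flt3 locus was examined as a source of strong gains in Flt3-ITD lists. Of 145 such gains, 1 (0.690%) lay within 20 Mb of Flt3, against 1.48% of all union regions. This argues against linked DNA as the source of most of these gains. A few linked gains are not excluded, since of the 135 gains in set 1 only 19 were absent from both wild-type lists.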
